A study of Mus musculus with 6 samples.

How the data were processed

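Whole transcriptome libraries of sorted mouse lung ILC2s were analysed, 3 cultured with PBS and 3 with TNFa. Per the labels' protocols, total RNA was isolated from the cultures, 10 ng of it was turned into cDNA, and libraries were made by the sequencer maker's standard procedure. The authors deposited estimated counts per gene, made with Partek's expectation-maximization quantification to an annotation model, per the file headers and file name; this method divides reads that match several genes among them, so the values need not be whole. The submitters' processing notes also list CASAVA 1.8.2, STAR and the genome build mm10, with no order or role. The annotation release, the filter on genes and whether counting used strand are not given in the sources used here. The deposited values were not scaled between libraries.

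The table held 21825 genes, each with a total of at least 10 over the 6 libraries, and 41.7% of its values were whole within 0.01. It held 0 further columns of values. Of the gene names, 21681 were found in GENCODE M21, which uses the same build, and 21201 genes had the same chromosome, start and end there once the end in the file was taken as 1 base past the last base. Transcript lengths and GC content came from that annotation. Gene types were those given in the deposited table, where 14696 genes were protein coding. Coordinates are mm10 and 1-based. Because reads of near-identical genes are shared out by the counting, values of gene families (Serpina3, immunoglobulin and T cell receptor constant genes, MHC genes, haemoglobins) are uncertain, and so are values of genes that overlap another gene on either strand.

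Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, leaving 15719. Libraries were scaled by TMM, and the quasi-likelihood test with robust estimation compared TNF with PBS. P-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05 and no fold threshold. Each log2 fold change is given with its SE, derived from the fitted value and its F statistic, and CPM values are TMM-scaled with mean and SD over 3 libraries. Gene lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 27 lists tested. Beside it stand camera with a correlation estimated for each list and fry. The replicate numbers are not shared between the groups, so no block was fitted. Principal components used log2 CPM with a prior count of 2.

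Totals of 25089415 to 32487004 counts per library set the precision: counting error is small for genes at 10 CPM or more, and the spread between 3 libraries limits the test. On data simulated from these libraries for the comparison of TNF with PBS, with 15719 genes of which 200 were changed, the test called 17.2% of genes changed 1.5-fold, 45.2% of those changed 2-fold and 73.4% of those changed 4-fold; 8 of 94 calls were false, and it made 0 calls when no gene was changed. The simulation drew genes independently, each with the same dispersion in every library. It held no library that stood apart and no genes that moved together, so these rates describe that simpler case. Replicates differed by far more than sampling noise (chi-square per degree of freedom from 15.5 to 114 within groups), and each library was counted as 1. Separate preparations of 1 RNA would exceed that noise as well, so this does not show that the libraries came from separate samples. The label of PBS replicate 2 marks it as a repeat; its correlations with the other PBS libraries were 0.972 and 0.973.

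The comparison, the tests, 28 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The lists covered noncanonical NF-kB genes, NF-kB subunits and targets, TNF receptor signalling, TNF superfamily and costimulation, anti-apoptotic and pro-apoptotic genes, effector cytokines, ILC2 identity and cell cycle. Further lists covered chemokines and their receptors, checkpoint and activation genes, immediate early genes, interferon response, MHC class I and II, glycolysis, oxidative phosphorylation, fatty acid metabolism, cholesterol synthesis and stress responses. Markers of other innate lymphocytes and NK cells, T cells, B cells, myeloid cells, mast cells with basophils and eosinophils, structural cells, erythroid cells and sex-linked genes completed them. The rule named the 8 genes with the largest log2 fold change in each direction among genes past the threshold with a mean of at least 10 CPM and no overlap between groups. It also took a set of TNF, NF-kB, cytokine and ILC2 genes whatever their call, up to 4 members of each list with a called gene, and the 2 most abundant markers of each other cell type. All remaining genes past the threshold, and 4 members of each list called as a set without a called gene, were added after seeing the data.

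Alternatives fixed beforehand were DESeq2's size factors, library size scaling alone, no filter, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, estimation without the robust option, a log2 fold threshold of 1, an adjusted p threshold of 0.01, the other list tests and leaving out each library in turn. Chosen after seeing the data were leaving out 5 genes that take ribosomal RNA reads, protein-coding genes alone, sample quality weights in limma-voom, and removing trends on transcript length, or on length and GC content, from each library.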

Results

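Group 2 innate lymphoid cells (ILC2s) are tissue lymphocytes that carry no rearranged antigen receptor and make type 2 cytokines such as IL-5 and IL-13. Here they were sorted from the lungs of BALB/c mice aged 6 weeks that had received 3 intraperitoneal doses of IL-33, 1 µg each, a cytokine that expands and activates these cells. The sorted cells were then cultured for 48 h in IL-2 and IL-7, 10 ng/mL of each, together with either 40 ng/mL TNFa, a cytokine that signals through 2 receptors to NF-kB, or its PBS vehicle. RNA was sequenced from 6 libraries, 3 per group, numbered 1 to 3 with PBS and 4 to 6 with TNF. The libraries held 29185442 to 30908757 counts assigned to genes with PBS and 25089415 to 32487004 with TNF (exact permutation test of the totals, two-sided p = 0.5; the smallest p that 3 against 3 libraries allow is 0.1). The labels do not say whether the libraries came from separate cultures or animals, so the p-values measure the spread between these libraries only.

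The comparison asked how TNF changed the transcriptome of lung ILC2s. The clearest single change was in Il9, the gene of a type 2 cytokine that acts on mast cells and on ILC2s themselves, which rose 4.90-fold (95% interval 4.00 to 6.01) from 25.2 ± 3.23 CPM with PBS to 124 ± 4.09 CPM with TNF (counts scaled to the size of the library, mean ± SD, n = 3 each). Genes of the NF-kB pathway rose with it: Nfkb2, which encodes the precursor of the NF-kB subunit p52, by 2.26-fold, Nfkbia, the inhibitor IkBa, by 2.17-fold, the receptor adaptor Traf1 by 1.65-fold and the ubiquitin ligase Birc3 (cIAP2) by 1.87-fold. Both lymphotoxin genes rose, Lta by 2.86-fold and Ltb by 2.06-fold. Icos, a costimulatory receptor of lymphocytes, and Cdc25b, a phosphatase that activates cyclin-dependent kinases, were the 2 genes that fell, by 0.78 and 0.74 on the log2 scale, to 517 ± 33.1 and 112 ± 10.5 CPM.

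In all, 16 of 15719 tested genes changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 14 higher and 2 lower with TNF. The strongest evidence was for Il9 (log2 fold change 2.29 ± 0.13, SE, adjusted p = 0.00017), followed by Lta (1.52 ± 0.12, adjusted p = 0.0022) and Serpina3g (1.52 ± 0.14, adjusted p = 0.0038). The other 13 genes had adjusted p-values from 0.024 to 0.048. All 16 were separated without overlap between the 3 TNF and the 3 PBS libraries, and 12 of them changed at least 2-fold. Over all tested genes 15.2% had no overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 1306 genes, 578 higher and 728 lower. The count changed whichever library was left out, which also leaves the test fewer libraries. It was 1, 3 and 2 without PBS replicates 1, 2 and 3, and 3, 67 and 5 without TNF replicates 4, 5 and 6. TNF replicate 5 stood apart from all other libraries, and without it the 67 genes divided into 38 higher and 29 lower and held all 16 of those above. DESeq2, an alternative fixed beforehand, called 218 genes on all 6 libraries, 108 higher and 110 lower, and these held all 16 as well. With a transcript length trend removed from each library, an alternative chosen after seeing the data, 16 genes were higher and 13 lower, and with length and GC trends removed 26 were higher and 13 lower.

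**Figure D1:**
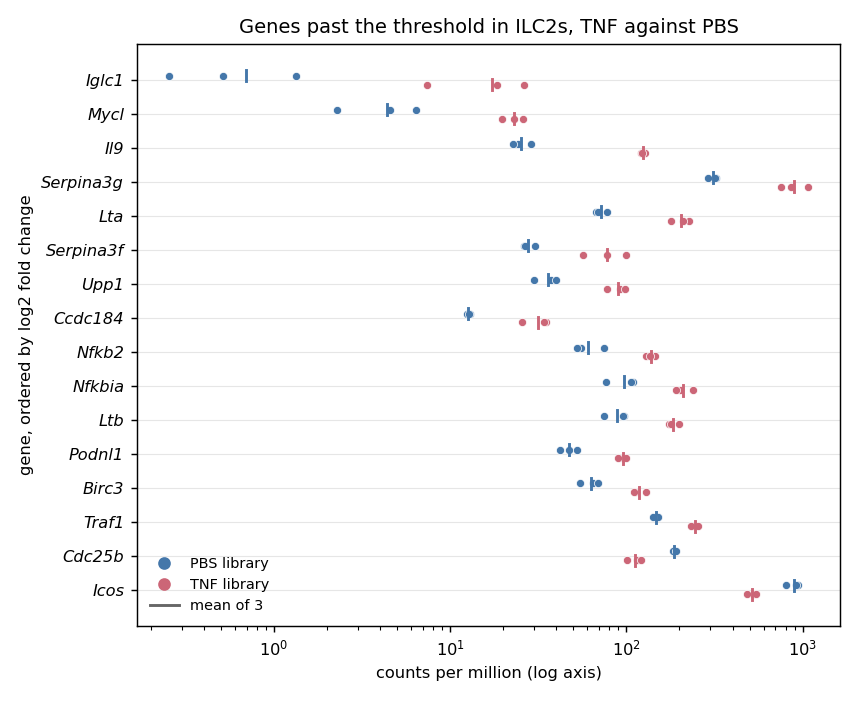
CPM (log axis) in each of the 6 libraries for the 16 genes that changed, ordered by log2 fold change. Blue points are PBS libraries, red points TNF libraries and short vertical lines the mean of 3; in every gene the groups do not overlap, from Iglc1 at the top (0.25 to 1.33 CPM against 7.35 to 26.2 CPM) to Icos at the bottom.

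The 16 genes include several outside the NF-kB and cytokine lists. Serpina3g and Serpina3f, serine protease inhibitor genes that lie close together on chromosome 12 (mm10, 104236245 to 104241939 and 104214544 to 104221129, both on the plus strand), rose 2.87-fold and 2.80-fold. The Serpina3 genes form a family of similar sequences, so reads can be divided wrongly among them. Upp1, uridine phosphorylase, rose 2.49-fold to 89.3 ± 10.7 CPM. Mycl, the transcription factor L-Myc, rose 5.20-fold from 4.40 ± 2.05 CPM. Podnl1 and Ccdc184 rose 2.01-fold and 2.47-fold. Iglc1, an immunoglobulin lambda constant gene, went from 0.697 ± 0.56 to 17.3 ± 9.46 CPM, or 24.8-fold with a 95% interval of 9.34 to 66.0. It is the only one of the 16 that is not annotated as protein coding, and it belongs to a family of near-identical copies, so its reads are uncertain too. The immunoglobulin genes Ighm and Igkc had log2 fold changes of -0.17 ± 0.38 and 0.28 ± 0.28 (adjusted p = 0.94 and 0.83).

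The NF-kB genes were examined as 2 lists fixed before the data were examined. All 8 members of the noncanonical NF-kB list had higher means with TNF, and the list rose as a set (camera, adjusted p = 8.4e-11; adjusted p = 0.106 with an estimated correlation). Nfkb2 and Birc3 passed the test over all genes, and 4 members passed when adjusted over the list alone, the other 2 being Relb (log2 fold change 0.87 ± 0.17, adjusted p = 0.15 over all genes) and the kinase Map3k14 (0.50 ± 0.17, adjusted p = 0.43). In the list of NF-kB subunits, inhibitors and target genes, 17 of 21 members had higher means and the list rose as a set (camera, adjusted p = 2.2e-06; adjusted p = 0.0904 with an estimated correlation). Nfkbia and Traf1 passed over all genes. Adjusted over the list alone, 8 members passed higher and 2 lower, the latter being Nfkb1, the precursor of p50 (370 ± 18.1 against 242 ± 28.8 CPM, adjusted p = 0.11 over all genes), and Nfkbiz. The stress gene Gadd45b stood at 0.88 ± 0.16 (adjusted p = 0.10), and Rela, the p65 subunit, at -0.03 ± 0.11 (adjusted p = 0.96). In the list of 18 TNF receptor signalling genes the median log2 fold change was -0.04 and no member passed (camera, adjusted p = 0.50). Of the receptors themselves, Tnfrsf1b was the more abundant, with 287 ± 15.9 CPM in PBS and 224 ± 52.2 in TNF (adjusted p = 0.61), while Tnfrsf1a stood at 3.84 ± 0.933 and 4.66 ± 0.681 CPM (adjusted p = 0.86).

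Among 20 ligands and receptors of the TNF superfamily and related costimulation, Lta and Ltb rose and Icos fell, and the other 17 did not pass over all genes. Adjusted over the list alone, 3 passed higher and 1 lower, Tnfsf10 (TRAIL; 0.46 ± 0.14, adjusted p = 0.39 over all genes) being the addition. The members went both ways, 11 higher and 9 lower, with a median log2 fold change of 0.09. Camera called the list higher as a set (adjusted p = 0.0082, or 0.154 with an estimated correlation), but not without TNF replicate 4 (adjusted p = 0.0786). Lta (mm10, chromosome 17, 35203165 to 35205351, minus strand) and Ltb (35194439 to 35196320, plus strand) flank Tnf (35199381 to 35202007, minus strand), whose own transcript was at 14.6 ± 2.45 CPM with PBS and 21.5 ± 2.18 with TNF (log2 fold change 0.56 ± 0.19, adjusted p = 0.43).

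Of the 12 effector cytokine and mediator genes tested, 11 had higher means with TNF, and the list rose as a set (camera, adjusted p = 3.2e-11; adjusted p = 0.0904 with an estimated correlation). Il9 (mm10, chromosome 13, 56479277 to 56482246, minus strand) passed over all genes, and 4 members passed when adjusted over the list alone: Il9, Csf2, Areg and Penk. Csf2, which encodes GM-CSF, missed the threshold over all genes at an adjusted p of 0.056, with 381 ± 38.8 CPM in PBS and 633 ± 43.8 in TNF (1.66-fold, 95% interval 1.40 to 1.96), and passed it without TNF replicate 5 (adjusted p = 0.018). The main type 2 cytokines did not pass. Il5, the most abundant, was at 4520 ± 448 CPM in PBS and 5442 ± 308 in TNF (log2 fold change 0.27 ± 0.10, adjusted p = 0.51), and Il13 at 114 ± 8.72 and 151 ± 41.7 CPM (0.41 ± 0.18, adjusted p = 0.57). Areg, encoding the epithelial growth factor amphiregulin, had a log2 fold change of 0.30 ± 0.10 (adjusted p = 0.43), Il4 of -0.17 ± 0.19 (adjusted p = 0.85) and Il6 of 0.07 ± 0.31 (adjusted p = 0.97).

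Genes that mark ILC2s moved the other way. Of 18 tested, 14 had lower means with TNF, and the list fell as a set with a median log2 fold change of -0.38 (camera, adjusted p = 1.7e-06; adjusted p = 0.0904 with an estimated correlation). No member passed over all genes, and 7 passed lower when adjusted over the list alone. These include Gata3, the transcription factor on which ILC2s depend (978 ± 71.8 against 705 ± 52.1 CPM, adjusted p = 0.20 over all genes), Il1rl1, the IL-33 receptor (616 ± 64.9 against 425 ± 49.8 CPM, adjusted p = 0.22), Arg1 (625 ± 23.5 against 426 ± 32.2 CPM, adjusted p = 0.10) and the IL-25 receptor chain Il17rb (log2 fold change -0.58 ± 0.16, adjusted p = 0.33). Rora, another ILC2 transcription factor, stood at -0.11 ± 0.09 (adjusted p = 0.79). In TNF replicate 5, the library that stood apart, the mean deviation of the list from the PBS mean was -0.43, against -0.11 and -0.24 in TNF replicates 4 and 6. T cell markers also fell as a set, with a median of -0.28 over 12 genes (camera, adjusted p = 0.0082; adjusted p = 0.154 with an estimated correlation), but not without TNF replicate 4 (adjusted p = 0.0786); the most abundant were Trbc2, at 242 ± 8.54 and 211 ± 22.7 CPM, and Trbc1, at 104 ± 9.1 and 87.1 ± 9.18 CPM, a pair of near-identical constant genes (adjusted p = 0.69 and 0.63). Trac was far less abundant, at 12.0 ± 0.329 CPM in PBS and 9.22 ± 1.21 in TNF. No T cell marker passed over all genes or when adjusted over the list alone, Foxp3 coming closest at -0.52 ± 0.16 (adjusted p = 0.39 over all genes).

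**Figure D2:**
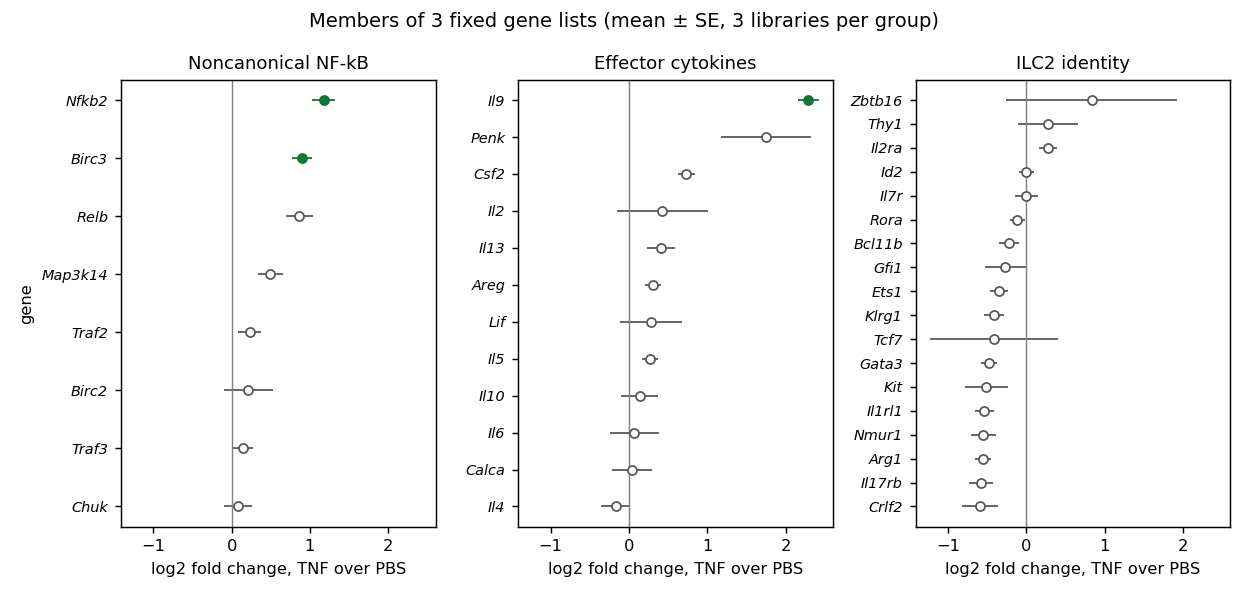
Log2 fold change, TNF over PBS, of each tested member of 3 gene lists, with bars of 1 SE and n = 3 libraries per group. Filled green points passed the test over all genes; all 8 noncanonical NF-kB genes and 11 of 12 cytokine genes lie above 0, and 14 of 18 ILC2 genes lie below it.

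Interferon-response genes rose as a set, with a median log2 fold change of 0.80 and 17 of 19 tested members higher (camera, adjusted p = 1.9e-14). The call is lost with an estimated correlation (adjusted p = 0.283), and the members moved together from library to library (estimated correlation 0.73). No member passed over all genes, and 14 passed when adjusted over the list alone. Among them were the chemokine gene Cxcl10 (0.324 ± 0.25 against 3.82 ± 1.42 CPM, adjusted p = 0.097 over all genes), the guanylate-binding protein gene Gbp5 (15 ± 3.75 against 37.1 ± 15 CPM, adjusted p = 0.21), Bst2 (log2 fold change 0.61 ± 0.15, adjusted p = 0.28) and Isg15 (1.22 ± 0.34, adjusted p = 0.34). The increase was largest in TNF replicate 6, where all 19 genes were at their highest of the 6 libraries and the median stood 1.45 above the PBS mean on the log2 scale, against 0.54 and 0.28 in TNF replicates 4 and 5. Without replicate 6 the median log2 fold change was 0.35. Genes of MHC class I presentation likewise rose as a set, 11 of 12 being higher with a median of 0.28 (camera, adjusted p = 1.8e-07; adjusted p = 0.283 with an estimated correlation). Here too TNF replicate 6 was highest, the mean of the list standing 0.20, 0.23 and 0.51 above the PBS mean in TNF replicates 4, 5 and 6, and the adjusted p was 0.0014 without replicate 6 and 0.00049 without PBS replicate 3. None of these passed over all genes and 5 did when adjusted over the list alone, among them the immunoproteasome subunit Psmb10 (86.7 ± 14.2 against 147 ± 20.1 CPM, adjusted p = 0.15 over all genes), Psme2 (0.56 ± 0.13, adjusted p = 0.21), Tapbp (0.61 ± 0.18, adjusted p = 0.36) and B2m (0.36 ± 0.09, adjusted p = 0.30).

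**Figure D3:**
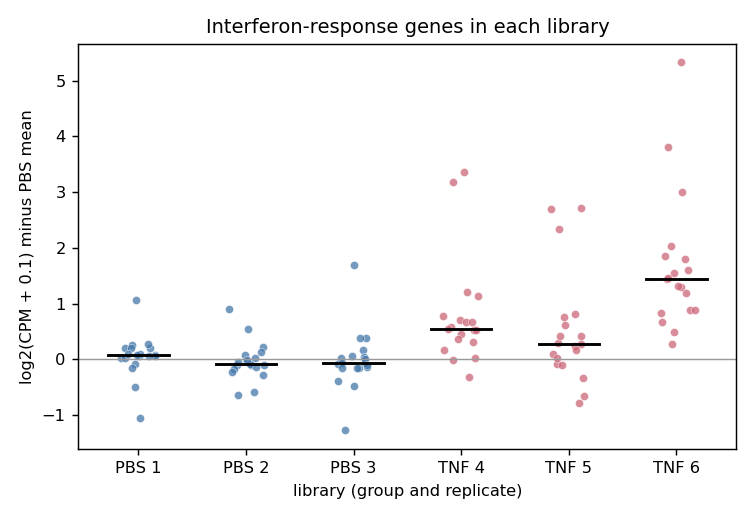
Log2(CPM + 0.1) of the 19 tested interferon-response genes in each library, minus the mean of the 3 PBS libraries; each point is a gene and each black bar the median of a library. The medians are 0.54, 0.28 and 1.45 in TNF replicates 4, 5 and 6.

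Survival and division genes gave few changes. Of 11 anti-apoptotic genes Birc3 alone rose (list: camera, adjusted p = 0.18), and adjusted over the list alone it was again the only one. Bcl2 stood at 71.8 ± 9.93 CPM in PBS and 82.9 ± 3.8 in TNF (adjusted p = 0.73), with log2 fold changes of -0.22 ± 0.11 for Mcl1 (adjusted p = 0.66) and -0.18 ± 0.14 for Bcl2l1 (adjusted p = 0.79). None of 17 pro-apoptotic genes passed, over all genes or over the list alone (camera, adjusted p = 0.50). The 38 cell cycle genes fell slightly as a set, 31 being lower with a median of -0.09 (camera, adjusted p = 0.0050; adjusted p = 0.530 with an estimated correlation), and no longer did so without TNF replicate 5 (adjusted p = 0.0581). None of them passed over all genes or when adjusted over the list alone. Examples were Foxm1 (91.3 ± 2.16 against 68.8 ± 11.6 CPM, adjusted p = 0.43), E2f2 (log2 fold change -0.40 ± 0.15, adjusted p = 0.50), Aurkb (-0.27 ± 0.10, adjusted p = 0.51) and Cdc20 (-0.23 ± 0.10, adjusted p = 0.56). Mki67, the usual marker of dividing cells, was at 474 ± 63.6 and 469 ± 90.3 CPM (adjusted p = 0.98).

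Of the 27 lists with enough tested members, 9 were called by camera, 6 higher and 3 lower. With an estimated correlation 0 lists were called, with 6 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 5: both NF-kB lists, the effector cytokines, the ILC2 markers and the T cell markers.

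Markers of other cell types were measured to see what else the sorted cultures held. The mast cell protease genes Tpsab1 (703 ± 66.0 CPM in PBS, 763 ± 53.5 in TNF) and Cma1 (218 ± 28.5 and 226 ± 16.5 CPM) were abundant in every library, and their list had a median log2 fold change of 0.04 (camera, adjusted p = 0.68; 0.014, higher with TNF, without TNF replicate 6). Of the genes of other innate lymphocytes and NK cells, Gzmb was at 153 ± 12.3 CPM with PBS and 87.5 ± 10.5 with TNF (log2 fold change -0.80 ± 0.12, adjusted p = 0.063), and Gzma at 50.4 ± 15 and 13.4 ± 5.93 CPM (-1.92 ± 0.32, adjusted p = 0.088). Adjusted over that list alone both passed lower, and 3 genes passed higher: Ifng, Ncr1 and Il22, named after their values were seen. Gzmb, Gzma and Il22 passed over all genes without TNF replicate 5 (adjusted p = 0.026, 0.0055 and 0.0073). That list had a median of -0.39 and a mean of 0.09 and was not called (camera, adjusted p = 0.50). The medians of the B cell, myeloid and structural lists were -0.36, -0.38 and 0.63 (camera, adjusted p = 0.27, 0.30 and 0.50), and these directions are not firm: camera put the B cell list higher without TNF replicate 5 (adjusted p = 0.98), the myeloid list higher without PBS replicate 2 (0.89) and the structural list lower with the filter at 5 CPM (0.50). Adjusted over these lists alone, Epcam passed lower (log2 fold change -0.95 ± 0.16, adjusted p = 0.088 over all genes; named after its values were seen) and no other member passed. Chil3 ranged from 17.7 to 56.9 CPM in PBS and from 0 to 33.1 in TNF, and Ly6c2 had a log2 fold change of 0.52 ± 0.30 (adjusted p = 0.70). Of the structural genes, the endothelial Pecam1 was at 94.7 ± 20.8 and 108 ± 34.9 CPM, and the club cell gene Scgb1a1 at 81.0 and 46.1 CPM in TNF replicates 4 and 6, 0.187 in replicate 5 and no more than 8.07 with PBS. The haemoglobin genes Hba-a1 and Hba-a2 stayed at or below 2.25 CPM.

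TNF replicate 5 stood apart in more than one measure. It had a score of 90.4 on the component that held 35.6% of the variance, where the other 5 libraries lay between -22.6 and -14.5, and its mean correlation with the others was 0.949, against 0.964 to 0.967 for each of the rest. Ribosomal protein genes took 4.29% of its counts (95% Wilson interval 4.29 to 4.30) against 2.70% to 3.03% elsewhere, and 5 genes that take reads from ribosomal RNA 4.94% (4.94 to 4.95) against 1.35% to 2.10%. Such intervals cover counting error only. Between the groups, exact permutation tests of the library measures gave two-sided p-values from 0.4 to 1.0, where the smallest possible is 0.1.

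**Figure D4:**
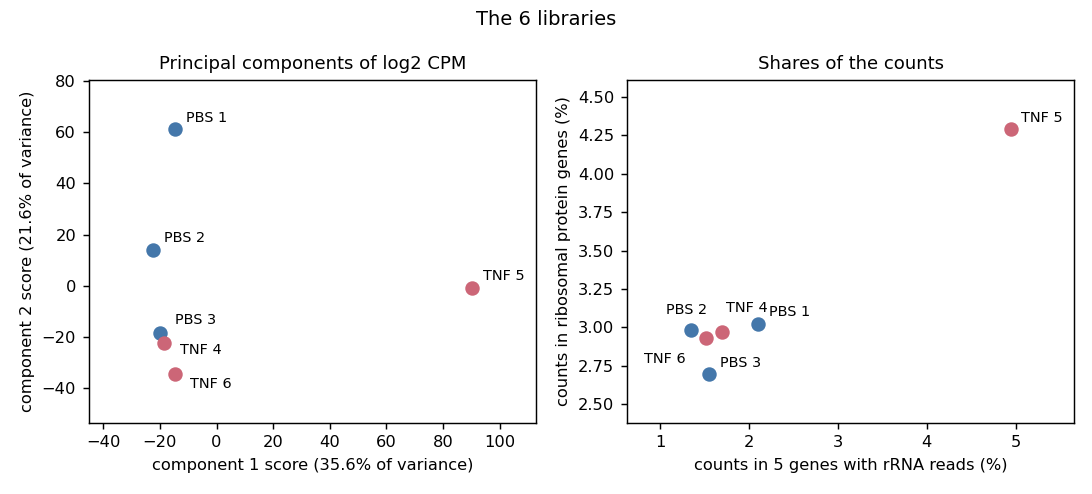
Left, scores of the 6 libraries on the first principal components of log2 CPM; right, percent of counts in 5 genes with ribosomal RNA reads against percent in ribosomal protein genes. Blue points are PBS and red points TNF libraries; TNF replicate 5 lies alone on the right of both panels, at a component score of 90.4 and a share of 4.94%.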

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

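The tests without the 5 genes with ribosomal RNA reads, on protein-coding genes, with quality weights and with trends removed were chosen after seeing the data. All 16 genes kept the direction of their change in every alternative that tested them, and Il9 passed the threshold in every one that was run. The number of genes changed was 16 with DESeq2's size factors, 13 with library size scaling (1 lower), 15 with limma-voom, 15 without robust estimation (1 lower), 16 without the 5 genes and 23 among protein-coding genes (18 higher, 5 lower). It was 3 (3 higher, 0 lower) with no filter, where more genes are tested, 25 (19 higher, 6 lower) with the filter at 5 CPM, where fewer are, 218 (108 higher, 110 lower) with DESeq2, 77 (41 higher, 36 lower) with quality weights, 29 (16 higher, 13 lower) with length trends removed and 39 (26 higher, 13 lower) with length and GC trends removed. At an adjusted p under 0.01 it was 3 (3 higher, 0 lower), and with a log2 threshold of 1 it was 12 (12 higher, 0 lower). Leaving out 1 library gave 1 to 67 genes, 1 to 38 higher and 0 to 29 lower; the highest came without TNF replicate 5, the lowest without PBS replicate 1, with 3 and 2 genes without PBS replicates 2 and 3 and 3 and 5 without TNF replicates 4 and 6. Of 9 lists called by camera, 0 were called with an estimated correlation (6 at an unadjusted p under 0.05) and 5 by fry; other alternatives called 7 to 11. With an estimated correlation the adjusted p was 0.106 for noncanonical NF-kB genes, 0.0904 for NF-kB targets, effector cytokines and ILC2 genes alike, 0.154 for the TNF superfamily and 0.530 for the cell cycle. The TNF superfamily list had an adjusted p of 0.178 with limma-voom, 0.110 with quality weights, 0.0659 with fry, and 0.00368 (without TNF replicate 5) to 0.0786 (without TNF replicate 4) when 1 library was left out. The cell cycle list had 0.245 with fry and 0.00253 (without PBS replicate 2) to 0.0581 (without TNF replicate 5), and the anti-apoptotic list passed at 0.0497 with the filter at 5 CPM. The causes of these differences between alternatives were not tested. Among uncalled values, 8 named genes and 10 lists changed sign in some alternative; the lists were checkpoint and activation, immediate early, MHC class II, glycolysis, oxidative phosphorylation, stress, B cell, myeloid, structural and sex-linked genes. Depth limits little here, since the smallest library has 25089415 counts; genes under 1 CPM are the exception.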

Other observations

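Several lists not described above were not called as sets, and none of their genes passed over all genes. The medians of their log2 fold changes and camera's adjusted p were 0.13 and 0.31 for chemokines and their receptors, -0.04 and 0.69 for checkpoint and activation genes, 0.05 and 0.50 for immediate early genes, and 0.12 and 0.61 for MHC class II. They were 0.04 and 0.50 for glycolysis, 0.05 and 0.50 for oxidative phosphorylation, -0.14 and 0.29 for fatty acid metabolism, and -0.10 and 0.14 for cholesterol synthesis. Stress genes gave -0.06 and 0.61, and sex-linked genes 0.17 and 0.58, while only 2 erythroid genes were tested, too few for a list test. The mean had the other sign than the median for immediate early genes (-0.01), MHC class II (-0.10) and stress genes (0.07). With length and GC trends removed, immediate early genes (adjusted p = 0.0064) and glycolysis (adjusted p = 0.015) were called higher, and without TNF replicate 6 cholesterol synthesis was called lower (adjusted p = 0.038). T cell markers were not called among protein-coding genes alone (adjusted p = 0.12). Adjusted over each list alone, 4 genes passed higher and 2 lower among chemokines and their receptors, 1 higher and 1 lower among checkpoint and activation genes (Pdcd1lg2 and Socs3), and 1 higher each among immediate early genes (Junb), glycolysis (Hk2) and fatty acid metabolism (Fabp5), the genes being named after their values were seen.

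Some of the genes that passed without TNF replicate 5 and not with all 6 libraries, chosen here after their values were seen, belong to known ILC2 or NF-kB biology. Il22, a cytokine better known from other innate lymphocytes, was at 7.59 to 10.6 CPM with PBS and 21.2 to 45.6 with TNF (log2 fold change 1.83 ± 0.29, adjusted p = 0.079; 2.04 ± 0.25, adjusted p = 0.0073 without that library). Tnfaip3, the NF-kB feedback gene A20, had 1.52 ± 0.17 (adjusted p = 0.0055) without it, against 1.21 ± 0.31 (adjusted p = 0.29) with all 6 libraries. Its level in TNF replicate 5 was 24.0 CPM, within the PBS range of 17.0 to 24.9, against 59.3 and 55.3 in TNF replicates 4 and 6. Relb had 0.94 ± 0.17 (adjusted p = 0.045) without TNF replicate 5. The chemokine receptor genes Ccr7 and Ccr4 were then higher, at 0.83 ± 0.14 (adjusted p = 0.034) and 0.85 ± 0.15 (adjusted p = 0.039), and Ccr2 was lower at -0.54 ± 0.09 (adjusted p = 0.033). Nfkb1 (-0.72 ± 0.09, adjusted p = 0.0061), Gzma (-2.33 ± 0.26, adjusted p = 0.0055), Ripk3 (-0.64 ± 0.10, adjusted p = 0.028) and Il9r, the receptor for IL-9 (-0.65 ± 0.11, adjusted p = 0.039), were lower. A call made without a library that was picked for standing apart is a description of the other 5 libraries.

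In the paragraphs that follow, the tests chosen after the result was seen were the count of genes over other splits, those of transcript length and of other cell types, fry and the estimated correlation without TNF replicate 6 with the limits for leaving out that library, Cochran's Q and the removal of length and GC trends. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 16 genes and the highest of the others 2, so that 1 of the 10 splits gave as many, the real one; for gene lists by camera the numbers were 9 and 5, and again 1 split gave as many.

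TNF replicate 5 stood apart from the rest, and no biological explanation from the design was tested, since no label sets this library apart. Leaving out the 5 genes that take ribosomal RNA reads left 99.9% of its summed squared deviation from the other TNF libraries, but 5 of 15719 genes cannot hold a large part of such a sum, so whether those reads go with the deviation stays open. Short transcripts were raised in it, by a median of 0.42 on the log2 scale below 1 kb. With a smooth trend on the longest annotated transcript of each gene removed, the SD of its deviations was still 0.428, against at most 0.301 in the other libraries. That trend is thus not the whole of the deviation. The transcripts expressed may be other than the longest, so length itself stays open. No marker list of another cell type had a summed CPM above the highest of the other 5 libraries (highest ratio 0.968). But abundant markers present in every library carry these sums and would hide a small share. By the median log2 deviation of their genes from the other TNF libraries, myeloid markers stood at 0.86 and B cell markers at -0.97. Markers of other innate lymphocytes and NK cells stood at -0.55, and the remaining lists lay between -0.33 and 0.05. Admixed cells thus stay open too. A difference in RNA quality, in library preparation or in the culture itself may lie behind it and was not tested.

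The rise of interferon-response genes was largest in TNF replicate 6, and whether it depends on that library stays open. Without it the median log2 fold change was 0.35 and 16 of 19 genes were higher. The adjusted p was then 1.3e-06 by camera but 0.13 by fry and 0.25 with an estimated correlation. With all libraries the list did not pass fry or the estimated correlation either (adjusted p = 0.27 and 0.28). Failing them without TNF replicate 6 therefore does not show dependence on that library. Ifng, the gene of the interferon that ILC1s, NK cells and T cells make, was at 12.2 CPM in that library, 4.07 and 1.98 in the other TNF libraries and at most 1.68 with PBS. A candidate source is a few NK or T cells that escaped the sort. Of their markers, 13 with low levels had a median excess in TNF replicate 6 of 0.10 (SE 0.35, from resampling the genes), too imprecise to decide. Single markers went both ways and do not decide it either. Gzma, Gzmb and Trbc2 were at their lowest there, but Trbc1, Trac, Cd28 and Foxp3 were at their lowest in another TNF library. These tests cannot separate a response of ILC2s to TNF from a response to interferon made by other cells.

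The fall of ILC2 genes may in principle reflect fewer ILC2s among the cells with TNF. That would lower all of the genes by a common factor only if other cells made none of them and TNF changed none of them. They differed by more than their errors, with Cochran's Q at 69.7 on 17 degrees of freedom (chi-square p = 2.5e-08 for a common fall). That p-value treats the genes as independent and their errors as known. Id2 and Il2ra had log2 fold changes of 0.00 ± 0.10 and 0.28 ± 0.11, against -0.47 ± 0.10 for Gata3. The 64 markers of other cell types had a median of -0.11 (SE 0.10, from resampling the genes), and the list medians went both ways. Of 6 such lists tested on all libraries, camera called 0 higher. It called the T cell markers lower (adjusted p = 0.0082, or 0.154 with an estimated correlation). Without TNF replicate 6 it called the mast cell, basophil and eosinophil markers higher (adjusted p = 0.014). The falls of the ILC2 genes were thus not equal, but a smaller share of ILC2s stays open. Genes that other cells make, or that TNF itself changes, would not fall by the common factor. Smooth trends on the length and GC content of the longest annotated transcript did not account for the fall. The transcripts expressed may be other than the longest, so length and GC content themselves stay open. With both removed the list fell with a camera adjusted p of 1.9e-08 and a median of -0.36, against -0.38. Lower expression of Gata3, Il1rl1, Arg1 and their like in TNF-treated ILC2s remains a hypothesis, found and tested on the same libraries, and the list test did not hold with an estimated correlation (adjusted p = 0.0904).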
